A study of Homo sapiens with 26 samples.

How the data were processed

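RNA sequencing measured gene expression in 26 samples of the human colon carcinoma line HCT116 and its knockout sublines. Per the labels, cells grew in DMEM with fetal bovine serum, total RNA was taken with a column kit, and reads were paired, 100 bases long. Per the submitters' processing notes, the authors aligned reads to build hg38 with STAR 2.5.2 and counted them per gene with featureCounts of Subread 1.6.3. The deposited values are raw counts per gene and per ERCC spike-in, with no normalisation. The strand setting, the annotation release and the library preparation are not given in the sources used here, nor are the dose and time of JQ1.

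The table held 58131 features, of which 58039 were genes and 92 ERCC transcripts; 37069 genes had at least 1 count. 22 columns were matched to 1 sample each by their names. 4 columns were matched to a group only. 3 of these carry a clone number for DKO that no sample title has, and they were taken as DKO-C2 by elimination, with replicates a, b and c. The other is a DKO-C1 JQ1 column whose number no title has, called replicate a. The labels name an ERCC spike-in for 14 samples, those of control and DKO with or without JQ1, and none for 12, the single knockouts. All 26 libraries nevertheless held ERCC counts. Gene counts per library ran from 17700864 to 19093094, ERCC counts from 193685 to 807887, and the mitochondrial share of gene counts from 4.55% to 8.62%. The 25 pairs of libraries within groups had a chi-square per degree of freedom of 1.41 to 13.2, so no pair was as close as counting alone. Whether replicates are separate cultures is not stated, and p values measure only the spread within groups, not between sublines. Floors for counts of 0 cover counting error only.

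Genes were tested with edgeR 4.0.16 (R 4.3.3) in a quasi-likelihood fit of all 26 libraries with 9 groups, TMM factors (0.956 to 1.02) and filterByExpr with a minimum count of 10 and a minimum total of 15, which left 17198 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. CPM use TMM effective library sizes. The comparisons were CDK8KO, CDK19KO and DKO against control, each as the mean of the sublines, CDK8KO against CDK19KO, DKO beyond the sum of both single knockouts, JQ1 in control, JQ1 in DKO-C1, and the difference of these JQ1 responses. Each subline was tested alone as well, and sublines with each other. ERCC factors were the ratios of total ERCC counts.

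Before the data were examined, 36 gene lists with 758 entries, the comparisons, a first set of alternatives and a rule for the named genes were fixed; all 758 entries were in the table and 654 were tested. Lists of at least 3 tested members were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, and with fry. The rule names CDK8 and CDK19 everywhere, and for 6 comparisons the 6 largest rises and 6 largest falls among called genes. These needed at least 5 CPM in a compared group, all libraries of 1 side above all of the other except in the interaction, and the same call in both sublines where there are 2. It adds 3 members each of the 5 lists with the lowest camera p. For CDK8KO against CDK19KO and for DKO beyond the sum it names the 5 largest rises and falls, and MYC and HEXIM1 are named for JQ1. Clone-based and uncharacterised noncoding names were passed over, as were genes of the Y chromosome. Some of the genes that the rule names are not reported here and are left out of the counts of named genes. A list is described wherever its camera adjusted p was under 0.05.

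Chosen after seeing the data was a set of 9785 genes with little shared sequence. These are protein-coding, share under 10% of their 50-base words (1 in 8 used) with transcripts of other genes in GENCODE v29, and overlap no exon of another gene on their strand; 17187 tested genes had a value for shared words. For DKO and for DKO beyond the sum, genes were named by the same rule in this set too. As the strand setting is not given, overlaps on the opposite strand remain uncertain.

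The fit was tested on simulated data with known changes: 26% to 68.0% of genes changed 1.25-fold were called over the 8 comparisons, 74.0% to 94.0% of those changed 1.5-fold, 80.0% to 100% of those changed 2-fold and all of those changed 4-fold. Of the calls, 2.07% to 7.65% fell on unchanged genes. In 200 random lists, tested for CDK8KO alone, camera gave p under 0.05 in 0. As comparisons share control libraries, correlations across genes were set beside 5 simulations with no effect and the same shared libraries. Alternatives were DESeq2 size factors, DESeq2 1.42.0, limma voom, no filter on low counts, a minimum of 5 CPM, ERCC factors, a block for the replicate number, only the libraries compared, each subline alone, and each library left out in turn. A minimum change of 2-fold, protein-coding genes and genes with little shared sequence were tried as well. ERCC factors for the single knockouts, for CDK8KO against CDK19KO, for DKO beyond the sum and for the counts in both sublines, and the last 2 gene sets were added after seeing the data. Splits of the samples into other groups of the same sizes were counted, 100 drawn where more exist.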

Results

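RNA was sequenced from 26 libraries of HCT116, a human colorectal carcinoma cell line, in 9 groups. CDK8 and its paralog CDK19 are the alternative kinases of the Mediator complex, which links transcription factors to RNA polymerase II. JQ1 is a small molecule that displaces BET proteins from acetylated chromatin. The groups were control cells (n = 3), control cells given JQ1 (n = 3), cells labelled as CDK8 knockouts (CDK8KO), CDK19 knockouts (CDK19KO) and knockouts of both genes (DKO), each as sublines C1 and C2 (n = 3 per subline), and subline DKO-C1 given JQ1 (n = 2). Per library, 23203 to 24939 genes had at least 1 count. 17198 of 58039 genes had enough counts to be tested. Within groups, log2 CPM (counts scaled to a common library size) of pairs of libraries correlated across genes with Pearson's r between 0.992 and 0.995. Log2 fold changes are given ± the standard error (SE), and CPM ± the standard deviation (SD); adjusted p values come from the quasi-likelihood test of edgeR.

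The direction of a change depends on the scaling. With library factors from the ERCC spike-in in place of those from the genes, the median log2 fold change of all genes shifted by -1.22 in CDK8KO, -1.65 in CDK19KO and -0.90 in DKO, each against control. The shift was 0.43 for CDK8KO against CDK19KO, 1.97 for DKO beyond the sum of the single knockouts, -0.37 for JQ1 in control cells, -0.27 for JQ1 in DKO-C1 and 0.0979 for the difference between these JQ1 responses. Every rise and fall in the text is therefore a change relative to the median gene. The labels name a spike-in for the control and DKO samples and not for the single knockouts. Single knockouts against control, and DKO beyond the sum, may thus also hold a difference between batches of libraries. CDK8KO against CDK19KO does not cross this label. For gene lists, a second p with the correlation estimated from the data is given where the call was then lost; lists without one kept their call.

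The first comparison asks how the RNA of the targeted genes stood in the knockouts. CDK8 (ENSG00000132964, chromosome 13, 26254104 to 26405238 of build hg38, plus strand) was at 89.0% of control in CDK8KO (log2 fold change -0.17 ± 0.0480, adjusted p = 0.00467), with 45.4 ± 1.77 CPM (SD, n = 6) against 50.9 ± 1.12 CPM (n = 3). It was at 75.5% of control in DKO (-0.41 ± 0.0483, adjusted p = 1.47e-09) and at 109.8% in CDK19KO (0.13 ± 0.0476, adjusted p = 0.0207). CDK19 (ENSG00000155111, chromosome 6, 110609978 to 110815958, minus strand) was at 80.3% of control in CDK19KO (-0.32 ± 0.0658, adjusted p = 0.000139), with 22.1 ± 3.78 CPM (SD, n = 6) against 27.3 ± 2.73 CPM (n = 3). It was higher than control in the other knockouts, at 126% in CDK8KO (adjusted p = 4.92e-05) and 131% in DKO (adjusted p = 9.4e-07). By subline, CDK8 was at 87.1% of control in CDK8KO-C1 (adjusted p = 0.0039) and 91.1% in CDK8KO-C2 (adjusted p = 0.0571), and CDK19 was at 69.3% in CDK19KO-C1 (adjusted p = 5.04e-07) and 93% in CDK19KO-C2 (adjusted p = 0.278). The rise of CDK8 in CDK19KO was not called in subline C1 alone (adjusted p = 0.0787), and was no longer called without control replicate 1 (adjusted p = 0.0791) or control replicate 2 (adjusted p = 0.0697). With ERCC factors the rises of CDK19 in CDK8KO and DKO and of CDK8 in CDK19KO turned into falls. The labels do not give the edited sites, so the RNA level alone does not check the knockouts.

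**Figure D1:**
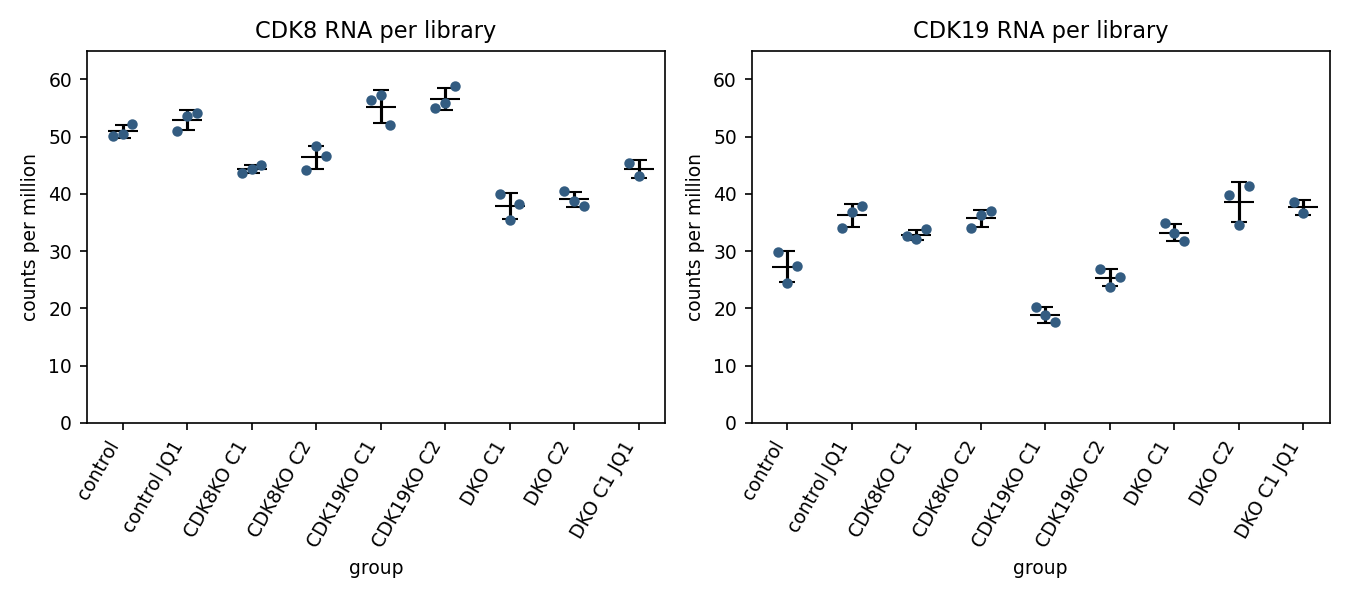
Normalised counts (CPM) of CDK8 and CDK19 in each library (points), with the group mean and SD. CDK8 lay at 75.5% and CDK19 at 131% of control in the libraries labelled DKO, relative to the median gene; with ERCC factors CDK19 was below control there.

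CDK8KO was compared with control to ask which genes depend on this kinase. The largest rises under the naming rule were those of MYL2, a myosin light chain (3.14 ± 0.170), TIMP3, an inhibitor of metalloproteinases (2.81 ± 0.112), and TAGLN, the actin-binding transgelin (2.52 ± 0.0900), with 18.8 ± 4.95 CPM (SD, n = 6) against 3.20 ± 0.112 CPM (n = 3). The lipocalin LCN2 (2.02 ± 0.162), TM4SF18 (2.46 ± 0.117) and SKIDA1 (2.06 ± 0.141) rose as well. The largest fall under the naming rule was that of ACSL5, which activates long-chain fatty acids (ENSG00000197142, chromosome 10, 112374018 to 112428380), by 4.27 log2 units (SE 0.0551), with 6.86 ± 1.88 CPM (SD, n = 6) against 129 ± 5.09 CPM (n = 3). The serotonin receptor HTR7 (-2.97 ± 0.0816), the semaphorin co-receptor NRP1 (-2.67 ± 0.129), the hyaluronan synthase HAS3 (-2.21 ± 0.0676), the monoamine oxidase MAOB (-2.11 ± 0.0597) and the protease inhibitor CSTA (-2.03 ± 0.140) fell. Adjusted p was at most 3.18e-13 for these 12 genes, and each moved the same way in both sublines. The sublines differed by over 1 log2 unit in some, at 3.78 and 1.14 in C1 and C2 for TM4SF18, 1.0 and 3.04 for LCN2, -1.05 and -4.88 for HTR7, -1.61 and -2.82 for HAS3 and -2.64 and -1.43 for CSTA.

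Of 24 integrated stress response genes, 20 fell and 0 rose (21 and 0 adjusted over the list alone, camera adjusted p = 1.26e-26). Among them were TRIB3 (-1.18 ± 0.0493), STC2 (-1.0 ± 0.0471) and CHAC1 (-1.66 ± 0.0816); CHAC1 degrades glutathione. Of 16 NRF2 antioxidant genes, 11 fell and 1 rose (11 and 1 adjusted over the list alone, camera adjusted p = 6.97e-08). The ferritin light chain FTL (-1.0 ± 0.0449) and NQO1 (-0.59 ± 0.0370), which share sequence with other genes, and the cystine transporter SLC7A11 (-0.88 ± 0.0687) fell. Of 17 Wnt target genes, 12 rose and 2 fell (13 and 2 adjusted over the list alone, camera adjusted p = 3.66e-05). BMP4 rose (1.32 ± 0.0452, 1.89 and 0.76 in C1 and C2), which was not called with ERCC factors (0.10, adjusted p = 0.445), whereas SOX9 (-0.56 ± 0.0400) and MYC (-0.63 ± 0.0513) fell. Of 18 mesenchymal genes, 8 rose and 2 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.000178). The collagen VI genes COL6A1 (0.71 ± 0.0488) and COL6A2 (0.66 ± 0.0533) rose relative to the median gene and were below control with ERCC factors. Of 27 nuclear-encoded oxidative phosphorylation genes, 19 fell and 0 rose (21 and 0 adjusted over the list alone, camera adjusted p = 0.0003, 0.443 with an estimated correlation). They included ATP5F1 (-0.35 ± 0.0413) and ATP5C1 (-0.27 ± 0.0387), which share sequence with other genes, and COX5B (-0.33 ± 0.0533).

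Of 14 antigen presentation genes, 7 rose and 2 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.0406, 0.52 with an estimated correlation). Of 23 cholesterol synthesis genes, 11 rose and 2 fell (11 and 2 adjusted over the list alone, camera adjusted p = 0.00277, 0.0657 with an estimated correlation). Of 36 MYC-driven ribosome biogenesis genes, 17 fell and 1 rose (18 and 1 adjusted over the list alone, camera adjusted p = 0.0131, 0.593 with an estimated correlation). Of 32 ribosomal protein genes, 17 fell and 0 rose (18 and 0 adjusted over the list alone, camera adjusted p = 0.00277, 0.752 with an estimated correlation). Of 30 S-phase entry genes, 14 rose and 4 fell (15 and 5 adjusted over the list alone, camera adjusted p = 0.0278, 0.51 with an estimated correlation). Of 13 replication-dependent histone genes, 6 fell and 0 rose (6 and 0 adjusted over the list alone, camera adjusted p = 0.0162, 0.123 with an estimated correlation). Of 15 intestinal identity genes, 7 rose and 5 fell (7 and 6 adjusted over the list alone, camera adjusted p = 0.0162, 0.0657 with an estimated correlation). Of 22 YAP/TEAD target genes, 15 rose and 2 fell (15 and 2 adjusted over the list alone, camera adjusted p = 0.0046, 0.51 with an estimated correlation). Of 3 fibroblast marker genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.00844, 0.0885 with an estimated correlation). The fibroblast marker FBLN1 (1.06 ± 0.0690) had group means of 20.01 CPM in control and 47.6 CPM and 36.4 CPM in sublines C1 and C2 (n = 3 each). Tested on genes with little shared sequence alone, the antigen presentation, ribosomal protein, S-phase entry, replication-dependent histone and intestinal identity lists were no longer called. With an estimated correlation on this set, the call for the Wnt target genes (adjusted p = 0.0621) was lost. In all, 6969 of 17198 genes were called in CDK8KO, 3350 higher and 3619 lower, and 590 changed at least 2-fold (294 up, 296 down). With ERCC library factors the split was 53 higher and 16205 lower.

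The same question was put to CDK19KO against control. COL17A1, a collagen of hemidesmosomes whose exons overlap another gene, rose (3.38 ± 0.134), as did TNFSF4, the OX40 ligand (2.74 ± 0.118), PODXL2 (2.72 ± 0.124), the axon guidance gene SEMA3A (2.56 ± 0.0714) and DNER (2.45 ± 0.106). KRT6A, a keratin that shares sequence with its paralogs, had 0.109 ± 0.110 CPM in control, 7.43 ± 0.569 CPM in CDK19KO-C1 and 1.23 ± 0.268 CPM in CDK19KO-C2 (n = 3 each). Among the falls were the glutamate transporter SLC1A3 (-3.57 ± 0.0866; ENSG00000079215, chromosome 5, 36606355 to 36688334), with 2.90 ± 2.11 CPM (SD, n = 6) against 25.9 ± 1.23 CPM (n = 3), CSTA (-3.22 ± 0.169) and the AMPK subunit PRKAA2 (-2.98 ± 0.127). ADGRF1 (-2.30 ± 0.0507), the mTORC1 inhibitor DDIT4 (-2.07 ± 0.0713), which shares sequence with other genes, and CHAC1 (-2.05 ± 0.0853) fell too. For these 12 genes adjusted p was at most 3.67e-13. Several differed by over 1 log2 unit between sublines, at 3.89 and 2.87 in C1 and C2 for COL17A1, 4.35 and 1.12 for TNFSF4, 0.67 and 4.24 for DNER, -2.43 and -4.71 for SLC1A3, -1.96 and -4.49 for CSTA, -1.70 and -2.90 for ADGRF1 and -1.21 and -2.92 for DDIT4.

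Among the integrated stress response genes, 21 of 24 fell and 0 rose (21 and 0 adjusted over the list alone, camera adjusted p = 6.32e-48). STC2 (-1.38 ± 0.0476) and PHGDH, the entry enzyme of serine synthesis (-1.19 ± 0.0416), were among them. Among the p53 target genes, 22 of 26 rose and 1 fell (23 and 1 adjusted over the list alone, camera adjusted p = 4.89e-20). CDKN1A, which encodes the cell cycle inhibitor p21, rose (1.38 ± 0.0523, 2.15 and 0.60 in C1 and C2), as did DDB2 (0.97 ± 0.0553) and PHLDA3 (1.11 ± 0.0702), which shares sequence and exons with another gene; with ERCC factors these 3 genes were below control. Among the cholesterol synthesis genes, 17 of 23 rose and 1 fell (17 and 1 adjusted over the list alone, camera adjusted p = 0.000709). LSS rose (0.47 ± 0.0424) and SQLE (-1.30 ± 0.0443, -0.80 and -1.81 in C1 and C2) fell. Among the Wnt target genes, 11 of 17 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 0.000709). BMP4 (0.54 ± 0.0442), DKK1 (1.09 ± 0.0864) and AXIN2 (0.45 ± 0.0668) rose. AXIN2 shares sequence and exons with another gene, and in subline C1 alone it was at -0.14 (adjusted p = 0.17). Among the antigen presentation genes, 9 of 14 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 0.00366, 0.26 with an estimated correlation). TAPBP (0.45 ± 0.0491) and TAP1 (0.53 ± 0.0614) rose. With ERCC factors the rises of LSS, BMP4, DKK1, AXIN2, TAPBP and TAP1 turned into falls.

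Among the glycolysis genes, 13 of 19 rose and 3 fell (14 and 3 adjusted over the list alone, camera adjusted p = 0.0201, 0.587 with an estimated correlation). Among the immediate early genes, 9 of 21 rose and 1 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.015, 0.529 with an estimated correlation). Among the MAPK output genes, 7 of 15 rose and 4 fell (8 and 4 adjusted over the list alone, camera adjusted p = 0.0108, 0.376 with an estimated correlation). Among the unfolded protein response genes, 10 of 19 fell and 1 rose (10 and 1 adjusted over the list alone, camera adjusted p = 0.00378). Among the autophagy and lysosome genes, 12 of 26 rose and 2 fell (12 and 3 adjusted over the list alone, camera adjusted p = 0.029, 0.457 with an estimated correlation). Among the NRF2 antioxidant genes, 7 of 16 fell and 3 rose (7 and 3 adjusted over the list alone, camera adjusted p = 0.00872, 0.0767 with an estimated correlation). Among the intestinal identity genes, 9 of 15 rose and 2 fell (11 and 2 adjusted over the list alone, camera adjusted p = 0.00439). Among the mitochondrially encoded genes, 10 of 13 fell and 0 rose (11 and 0 adjusted over the list alone, camera adjusted p = 0.00788, 0.635 with an estimated correlation). Mitochondrially encoded counts made up 5.45% ± 0.795 (SD, n = 3) of gene counts in CDK19KO-C1 and 6.01% ± 0.264 in CDK19KO-C2, against 7.41% ± 0.724 in control. The antigen presentation genes, glycolysis genes, immediate early genes, MAPK output genes, autophagy and lysosome genes, NRF2 antioxidant genes, intestinal identity genes and mitochondrially encoded genes were no longer called when tested on genes with little shared sequence alone. With an estimated correlation on this set, the calls for the Wnt target genes (adjusted p = 0.207), cholesterol synthesis genes (0.207), unfolded protein response genes (0.06) and intestinal identity genes (0.211) were lost. In all, 7390 of 17198 genes were called in CDK19KO, 3615 higher and 3775 lower, and 664 changed at least 2-fold (200 up, 464 down). ERCC factors gave a split in which 33 were higher and 16816 lower.

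CDK8KO and CDK19KO were compared directly, by averages over their sublines, to ask where the paralogs differ. MYL2 (4.70 ± 0.166), SLC1A3 (3.67 ± 0.0770), the cardiac and slow-muscle troponin gene TNNC1 (3.33 ± 0.127) and GFY (2.93 ± 0.153) were higher in CDK8KO. ACSL5 (-5.06 ± 0.0496), PODXL2 (-4.80 ± 0.130), COL17A1 (-3.76 ± 0.109), HTR7 (-3.41 ± 0.0698) and PRDM1 (-3.21 ± 0.228), a transcriptional repressor at low counts, were lower in CDK8KO. Adjusted p was at most 3.8e-15 for these genes, with n = 6 on each side. GFY was at 2.24 and 3.61 between the C1 and the C2 sublines, and HTR7 at -2.01 and -4.81. TIMP3 had 22.2 ± 1.38 CPM and 14 ± 0.301 CPM in the CDK8KO sublines C1 and C2, and 9.28 ± 0.931 CPM and 0.0181 ± 0.0314 CPM in the CDK19KO sublines (n = 3 each), against 2.5 ± 0.160 CPM in control. The last CDK19KO value rests on 1 count, and the TIMP3 difference between the knockouts was 1.26 between the C1 sublines and fitted at 9.13 between the C2 sublines. CDK8 was lower (-0.30 ± 0.0392, adjusted p = 2.93e-08) and CDK19 higher (0.65 ± 0.0530, adjusted p = 2.38e-13) in CDK8KO than in CDK19KO; with ERCC factors the CDK8 difference was not called (0.13, adjusted p = 0.257).

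Rose and fell stand here for higher and lower in CDK8KO. Among the p53 target genes, 24 of 26 fell and 1 rose (24 and 1 adjusted over the list alone, camera adjusted p = 8.94e-17). Among the mesenchymal genes, 9 of 18 rose and 3 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.00105). Among the unfolded protein response genes, 13 of 19 rose and 2 fell (13 and 2 adjusted over the list alone, camera adjusted p = 0.00371). Among the integrated stress response genes, 17 of 24 rose and 3 fell (17 and 3 adjusted over the list alone, camera adjusted p = 0.00105, 0.28 with an estimated correlation). Among the interferon response genes, 13 of 28 fell and 3 rose (14 and 3 adjusted over the list alone, camera adjusted p = 0.0295, 0.28 with an estimated correlation). Among the glycolysis genes, 12 of 19 fell and 4 rose (13 and 4 adjusted over the list alone, camera adjusted p = 0.0227, 0.538 with an estimated correlation). Among the immediate early genes, 12 of 21 fell and 4 rose (12 and 4 adjusted over the list alone, camera adjusted p = 0.00169, 0.456 with an estimated correlation). Among the MYC-driven ribosome biogenesis genes, 20 of 36 fell and 4 rose (20 and 4 adjusted over the list alone, camera adjusted p = 0.0165, 0.476 with an estimated correlation). Among the ribosomal protein genes, 21 of 32 fell and 0 rose (21 and 0 adjusted over the list alone, camera adjusted p = 0.0159, 0.667 with an estimated correlation). Among the replication-dependent histone genes, 8 of 13 fell and 1 rose (8 and 1 adjusted over the list alone, camera adjusted p = 0.00371, 0.0947 with an estimated correlation). Among the autophagy and lysosome genes, 14 of 26 fell and 4 rose (15 and 4 adjusted over the list alone, camera adjusted p = 0.04, 0.476 with an estimated correlation). Among the NRF2 antioxidant genes, 11 of 16 fell and 3 rose (11 and 3 adjusted over the list alone, camera adjusted p = 0.0321, 0.28 with an estimated correlation). Among the YAP/TEAD target genes, 16 of 22 rose and 3 fell (17 and 3 adjusted over the list alone, camera adjusted p = 0.000369, 0.353 with an estimated correlation). Among the nuclear-encoded oxidative phosphorylation genes, 14 of 27 fell and 1 rose (15 and 1 adjusted over the list alone, camera adjusted p = 0.0208, 0.538 with an estimated correlation). Among the mitochondrially encoded genes, 12 of 13 rose and 0 fell (13 and 0 adjusted over the list alone, camera adjusted p = 0.000369, 0.476 with an estimated correlation). On genes with little shared sequence alone, the interferon response, glycolysis, MYC-driven ribosome biogenesis, ribosomal protein and autophagy and lysosome lists were no longer called. Nor were the NRF2 antioxidant, nuclear-encoded oxidative phosphorylation and mitochondrially encoded lists. With an estimated correlation on this set, the calls for the unfolded protein response genes (adjusted p = 0.161) and mesenchymal genes (0.161) were lost. In all, 8098 of 17198 genes differed, 4067 higher and 4031 lower in CDK8KO, 757 of them at least 2-fold (461 up, 296 down). ERCC factors gave a split in which 12141 were higher and 420 lower.

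The libraries labelled DKO were compared with control to ask what follows when both kinases are targeted. Among genes with little shared sequence, a set chosen after seeing the data, the largest rises were those of TM4SF1, ANKRD1, TM4SF18, SERTAD4 and CTGF, together with POLR2F. TM4SF1, a tetraspanin-like membrane protein (ENSG00000169908, chromosome 3, 149369022 to 149377865), had 0 counts in the 3 control libraries and 34.0 ± 17.6 CPM (SD, n = 6) in DKO, at least 212-fold higher with a floor of 3 counts per library. The YAP targets ANKRD1 (6.78 ± 0.232) and CTGF (5.69 ± 0.154), TM4SF18 (6.62 ± 0.0873) and SERTAD4 (6.31 ± 0.171) rose. POLR2F, an RNA polymerase subunit gene overlapped on the opposite strand, was at 7.02 ± 0.145. For it, a difference in counting of the libraries labelled DKO cannot be told from a change of its RNA. ACSL5 (-5.28 ± 0.0610, 3.33 ± 0.615 CPM (SD, n = 6) against 129 ± 5.09 CPM (n = 3)), the transcription factor MEF2C (-5.21 ± 0.152), the annexin ANXA10 (-4.60 ± 0.224) and HTR7 (-3.99 ± 0.0838) fell. The remaining falls were those of PABPC3 (-3.92 ± 0.0677) and UQCRHL (-3.55 ± 0.0724), which are retrocopies of other genes. For these 12 genes adjusted p was at most 4.46e-19.

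Of 18 mesenchymal genes, 15 rose and 1 fell (16 and 1 adjusted over the list alone, camera adjusted p = 1.22e-09). TAGLN (5.31 ± 0.0763), fibronectin FN1 (2.92 ± 0.0717) and SPARC (5.5 ± 0.196) rose; SPARC had 0.305 ± 0.118 CPM in control, 54.7 ± 1.76 CPM in DKO-C1 and 3.60 ± 0.550 CPM in DKO-C2 (n = 3 each). Of 3 fibroblast marker genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.00684, 0.168 with an estimated correlation). FBLN1 (2.70 ± 0.0670) had group means of 20.01 CPM in control and 115 CPM and 147 CPM in DKO-C1 and DKO-C2 (n = 3 each). Of 22 YAP/TEAD target genes, 21 rose and 0 fell (21 and 0 adjusted over the list alone, camera adjusted p = 1.22e-09, 0.137 with an estimated correlation). CRIM1 (2.23 ± 0.0577) and ASAP1 (1.03 ± 0.0480) rose with ANKRD1; with ERCC factors ASAP1 was not called (0.13, adjusted p = 0.34). Of 18 TGF-beta/SMAD target genes, 12 rose and 4 fell (12 and 4 adjusted over the list alone, camera adjusted p = 8.6e-05, 0.184 with an estimated correlation). PMEPA1 (4.51 ± 0.124) and SMAD6 (2.31 ± 0.0813) rose. Of 36 MYC-driven ribosome biogenesis genes, 33 fell and 1 rose (33 and 1 adjusted over the list alone, camera adjusted p = 8.6e-05, 0.307 with an estimated correlation). ODC1 (-1.25 ± 0.0353) and POLR1B (-0.72 ± 0.0428) fell. NOP2, which shares sequence and exons, was at -5.69 ± 0.0591, under the limit given for POLR2F. Of 14 antigen presentation genes, 14 rose and 0 fell (14 and 0 adjusted over the list alone, camera adjusted p = 0.00203, 0.301 with an estimated correlation). TAPBP (0.90 ± 0.0493), B2M (0.56 ± 0.0419) and HLA-B (0.83 ± 0.0487), which shares sequence and exons with another gene, rose. With ERCC factors B2M was called below control, and TAPBP (adjusted p = 0.991) and HLA-B (-0.0667, adjusted p = 0.625) were not called.

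Of 15 MAPK output genes, 10 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.0136, 0.394 with an estimated correlation). Of 24 integrated stress response genes, 19 fell and 3 rose (20 and 3 adjusted over the list alone, camera adjusted p = 0.00684, 0.307 with an estimated correlation). Of 19 unfolded protein response genes, 14 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 0.0406, 0.168 with an estimated correlation). Mitochondrially encoded counts made up 5.43% ± 0.265 (SD, n = 3) of gene counts in DKO-C1 and 4.99% ± 0.426 in DKO-C2. Tested on genes with little shared sequence alone, the unfolded protein response genes were no longer called. Called there and not over all genes were the Wnt (adjusted p = 0.0344), NF-kappaB (0.00899) and mitotic lists (0.0286), higher, and the ribosomal protein (0.0183) and oxidative phosphorylation lists (0.0211), lower. These were not called there with an estimated correlation, whereas the YAP/TEAD (0.014) and TGF-beta/SMAD lists (0.0447) were. In all, 10579 of 17198 genes were called in DKO, 5064 higher and 5515 lower, 2858 of them at least 2-fold (1046 up, 1812 down). With ERCC library factors the split was 585 higher and 14316 lower. Of the genes with little shared sequence, 6542 of 9785 were called, 3131 higher and 3411 lower, 899 of them at least 2-fold (616 up, 283 down).

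Processed pseudogenes, the retrocopies of mRNAs, were lower in every library labelled DKO. Their share of gene counts lay between 0.182% and 0.208% in the 8 libraries labelled DKO and between 2.24% and 2.76% in the other 18. The median log2 fold change of 1346 processed pseudogenes was -3.90 in DKO (10th to 90th percentile -5.83 to -0.48), -0.11 in CDK8KO and -0.0660 in CDK19KO, and that of 9785 genes with little shared sequence was 0.0570 in DKO. Over all genes, most of the largest changes under the naming rule were in genes that share sequence or exons with another gene. WDR83OS, COG8 and ECE2, whose sequence is shared or overlapped, had 0 counts in the 6 DKO libraries and were at least 209-fold, 97.1-fold and 68.3-fold lower with a floor of 3 counts per library. PTP4A1 had 0.0975 ± 0.0623 CPM (SD, n = 6) against 377 ± 5.64 CPM (n = 3), CDC42EP2 0.0530 ± 0.0880 CPM (SD, n = 6) against 22.9 ± 1.12 CPM (n = 3), and the GTPase gene CDC42 0.796 ± 0.176 CPM (SD, n = 6) against 227 ± 1.58 CPM (n = 3). PYURF had 27.7 ± 2.07 CPM (SD, n = 6) against 0.0885 ± 0.0596 CPM (n = 3). These 4 genes share sequence or exons as well.

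**Figure D2:**
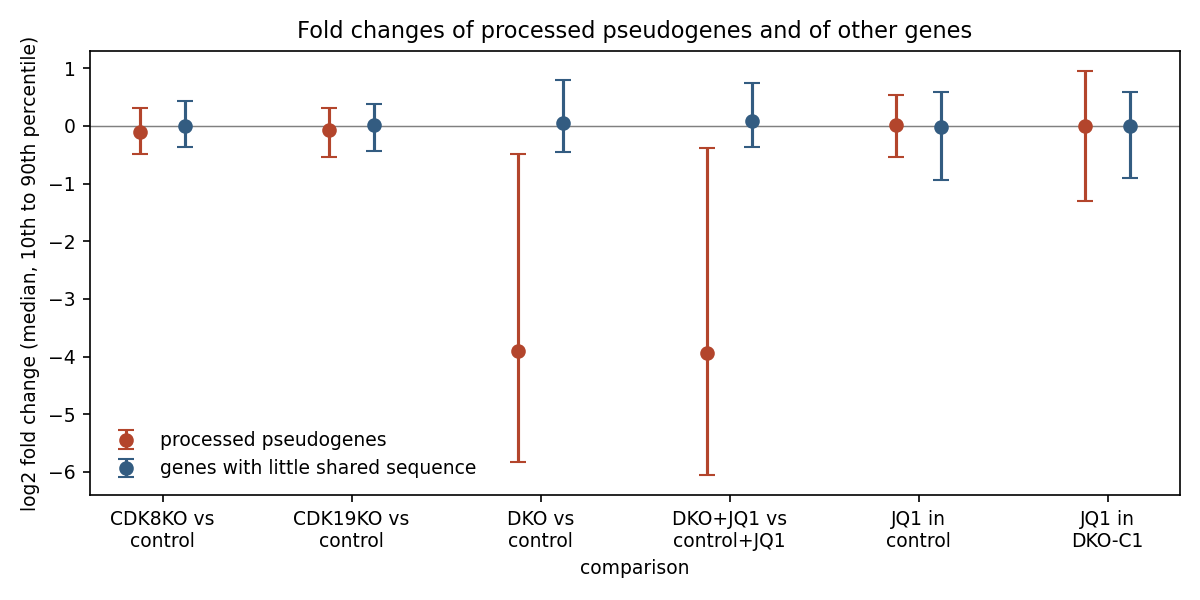
Median (points) and 10th to 90th percentile (bars) of the log2 fold change, relative to the median gene, of processed pseudogenes and of genes with little shared sequence in 6 comparisons. Processed pseudogenes lay at a median of -3.90 in DKO and -0.11 in CDK8KO.

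The change in DKO beyond the sum of the single knockouts, on the log2 scale, asks whether the kinases can stand in for each other. Among genes with little shared sequence, POLR2F (7.57 ± 0.601, 6.58 and 8.57 in C1 and C2), under the limit given for it in DKO, and the transcription factor CREB5 (5.62 ± 0.513) lay above the sum. TWIST1, DCLK1 and EDN1 lay above it too. They are given no folds beyond the sum, since TWIST1 in CDK19KO and DCLK1 and EDN1 in CDK19KO-C1 were at or near 0 counts. TWIST1, a transcription factor of mesenchymal cells, had 0 counts in the 6 CDK19KO libraries and was at 0.91 ± 0.168 in DKO. The kinase gene DCLK1 had 2.73 ± 0.998 CPM in control, 0.0184 ± 0.0319 CPM and 3.97 ± 0.530 CPM in CDK19KO-C1 and C2, and 28.4 ± 1.17 CPM and 27.7 ± 0.532 CPM in DKO-C1 and C2 (n = 3 each). The endothelin gene EDN1 had 0.593 ± 0.257 CPM in control, 0.0186 ± 0.0321 CPM and 1.42 ± 0.143 CPM in CDK19KO-C1 and C2, and 12.4 ± 0.735 CPM and 17.2 ± 2.03 CPM in DKO-C1 and C2. TTC22 (-4.03 ± 0.547), TNFSF4 (-3.83 ± 0.175), PODXL2 (-3.83 ± 0.372), the growth factor gene EPGN (-3.88 ± 0.782) and the retrocopy PABPC3 (-3.53 ± 0.0844) lay below the sum. For EPGN, TNFSF4 and PODXL2 the change in CDK19KO alone, a mean over its 2 sublines, was 3.77, 2.74 and 2.72. EPGN was raised in CDK19KO-C1 alone, and among the C2 sublines its departure from the sum was lost (-0.35, adjusted p = 0.798). TNFSF4 and PODXL2 rose more in CDK19KO-C1 than in C2, and TTC22 was below control in CDK8KO-C1 and above it in CDK8KO-C2. TNFSF4 (2.48 CPM in control) had 32.7 and 1.92 CPM in CDK8KO-C1 and C2, and 13.2 and 1.03 CPM in DKO-C1 and C2. Adjusted p was at most 5.12e-05 for these 10 genes.

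In these counts, rose and fell stand for above and below the sum. Among the mesenchymal genes, 13 of 18 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 0.00114). Among the YAP/TEAD target genes, 19 of 22 rose and 1 fell (19 and 1 adjusted over the list alone, camera adjusted p = 7.64e-07, 0.169 with an estimated correlation). Among the integrated stress response genes, 20 of 24 rose and 1 fell (20 and 1 adjusted over the list alone, camera adjusted p = 1.53e-08). Among the p53 target genes, 22 of 26 fell and 2 rose (22 and 2 adjusted over the list alone, camera adjusted p = 4.38e-05). Among the unfolded protein response genes, 17 of 19 rose and 0 fell (17 and 0 adjusted over the list alone, camera adjusted p = 0.00114). Among the TGF-beta/SMAD target genes, 12 of 18 rose and 2 fell (12 and 2 adjusted over the list alone, camera adjusted p = 0.00177, 0.274 with an estimated correlation). Among the MYC-driven ribosome biogenesis genes, 25 of 36 fell and 3 rose (25 and 4 adjusted over the list alone, camera adjusted p = 0.00666, 0.585 with an estimated correlation). Among the NRF2 antioxidant genes, 9 of 16 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.0126, 0.113 with an estimated correlation). On genes with little shared sequence, cholesterol synthesis (adjusted p = 4.55e-05, 0.0294 with an estimated correlation), glycolysis (0.0315) and S-phase entry genes (0.0105) were called below the sum as well, the last pair not with an estimated correlation, whereas the YAP/TEAD list was (0.0272). In all, 10185 of 17198 genes departed from the sum, 5051 above and 5134 below it, 2946 of them at least 2-fold (1225 above, 1721 below). ERCC factors gave a split in which 15473 were higher and 1035 lower. Of the genes with little shared sequence, 6138 departed from the sum, 3207 above and 2931 below it, 865 at least 2-fold (607 above, 258 below). CDK8 lay below the sum (-0.37 ± 0.0625) and CDK19 above it (0.38 ± 0.0824); with ERCC factors CDK8 lay above it, and among the C2 sublines CDK19 was not called (0.21, adjusted p = 0.0834). Over all genes, the naming rule gave PYURF, ATRIP, POLR2F, DCLK1 and ITGBL1 above and PTP4A1, WDR83OS, COG8, ECE2 and CDC42EP2 below the sum, of which all but POLR2F and DCLK1 share sequence or exons with another gene, so no folds are given for those. Of the DKO sublines without JQ1, ITGBL1 was above control in DKO-C1 alone, with 0.466 ± 0.0915 CPM in control, 5.40 ± 0.414 CPM in DKO-C1 and 0.124 ± 0.0283 CPM in DKO-C2 (n = 3 each), and had 0 counts in CDK8KO-C2.

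JQ1 was compared with no JQ1 in control cells, to measure the response to BET displacement in cells not targeted for either kinase. EFR3B rose most under the naming rule (4.39 ± 0.176; ENSG00000084710, chromosome 2, 25042130 to 25159137), with 15.1 ± 1.72 CPM (SD, n = 3) against 0.712 ± 0.290 CPM (n = 3). The membrane adaptor PAG1 (3.37 ± 0.124), the histone gene HIST2H2BE (3.25 ± 0.211), CLIC3 (2.85 ± 0.168), the interferon regulator IRF7 (2.83 ± 0.138) and TEX14 (3.15 ± 0.132), whose exons overlap another gene, rose. The keratins KRT7 (-4.60 ± 0.193) and KRT23 (-3.96 ± 0.151), ADGRF1 (-4.55 ± 0.0803), NRP1 (-4.18 ± 0.200), NAV3 (-4.17 ± 0.152) and ZNF532 (-3.93 ± 0.113) fell. KRT7 had 1.92 ± 0.184 CPM (SD, n = 3) against 46.8 ± 12 CPM (n = 3). MYC fell (-0.86 ± 0.0611, adjusted p = 6.79e-15) and HEXIM1, the inhibitor of P-TEFb, rose (1.24 ± 0.0481, adjusted p = 1.51e-23); HEXIM1 shares sequence with another gene. For the other 12 genes adjusted p was at most 2.01e-16. CDK19 rose (0.41 ± 0.0724, adjusted p = 6.82e-06), which was lost with ERCC factors (0.0486, adjusted p = 0.815), and CDK8 was at 0.0542 ± 0.0552 (adjusted p = 0.422).

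Of 13 replication-dependent histone genes, 10 rose and 0 fell (10 and 0 adjusted over the list alone, camera adjusted p = 1.7e-06). HIST1H2BD (2.61 ± 0.133), HIST1H1C (2.13 ± 0.109) and HIST1H2AC (2.27 ± 0.122) rose. Of 16 BET and P-TEFb genes, 10 rose and 0 fell (10 and 1 adjusted over the list alone, camera adjusted p = 4.99e-05). ELL2, an elongation factor (0.93 ± 0.0555), and BRD2 (0.71 ± 0.0422), which shares sequence with other genes, were among them. Of 6 neural marker genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.00028). MAP2 had 6.25 ± 0.420 CPM without and 42.8 ± 2.91 CPM with JQ1 (n = 3 each); ENO2 (0.99 ± 0.0588) and TUBB3 (1.09 ± 0.121), which shares sequence and exons with another gene, rose. Of 26 autophagy and lysosome genes, 18 rose and 4 fell (19 and 4 adjusted over the list alone, camera adjusted p = 5.84e-06, 0.0774 with an estimated correlation). MAP1LC3B (0.98 ± 0.0491), the lysosomal sialidase NEU1 (1.34 ± 0.0742) and ATG2A (1.29 ± 0.0757) rose. Of 24 integrated stress response genes, 19 fell and 3 rose (19 and 3 adjusted over the list alone, camera adjusted p = 3.97e-05, 0.0774 with an estimated correlation). TRIB3 (-1.58 ± 0.0613), STC2 (-1.40 ± 0.0579) and DDIT4 (-1.43 ± 0.0800), which shares sequence with other genes, fell.

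Of 18 NF-kappaB inflammatory genes, 10 fell and 1 rose (10 and 1 adjusted over the list alone, camera adjusted p = 0.00471, 0.0774 with an estimated correlation). Of 26 p53 target genes, 14 rose and 5 fell (15 and 6 adjusted over the list alone, camera adjusted p = 0.032, 0.0774 with an estimated correlation). Of 21 immediate early genes, 13 rose and 3 fell (13 and 3 adjusted over the list alone, camera adjusted p = 0.00172, 0.408 with an estimated correlation). Of 23 cholesterol synthesis genes, 14 fell and 4 rose (15 and 4 adjusted over the list alone, camera adjusted p = 0.032, 0.175 with an estimated correlation). Of 36 MYC-driven ribosome biogenesis genes, 25 fell and 1 rose (25 and 2 adjusted over the list alone, camera adjusted p = 0.00565, 0.479 with an estimated correlation). Of 16 NRF2 antioxidant genes, 10 rose and 2 fell (10 and 2 adjusted over the list alone, camera adjusted p = 0.00777, 0.0774 with an estimated correlation). Tested on genes with little shared sequence alone, the p53 target, cholesterol synthesis, MYC-driven ribosome biogenesis and NRF2 antioxidant lists were no longer called. With an estimated correlation on this set, the calls for the BET and P-TEFb genes (adjusted p = 0.0617) and neural marker genes (0.0617) were lost. In all, 9619 of 17198 genes were called for JQ1 in control cells, 4624 higher and 4995 lower, 1952 at least 2-fold (532 up, 1420 down). With ERCC library factors the split was 800 higher and 7679 lower.

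The same contrast in DKO-C1 (n = 2 with JQ1, n = 3 without) measures the JQ1 response in cells labelled as lacking both kinases. The reductase gene DHRS2 rose (3.85 ± 0.0998), with 49.8 ± 0.0260 CPM (SD, n = 2) against 3.46 ± 0.447 CPM (n = 3). PAG1 (3.73 ± 0.129), EFR3B (3.72 ± 0.129), TEX14 (3.67 ± 0.157), HIST1H2AC (3.59 ± 0.152) and the immediate early transcription factor EGR1 (3.09 ± 0.317) rose. The growth factor gene FGF1 had 6.72 ± 0.294 CPM without and 0.109 ± 0.0763 CPM with JQ1. ADGRF1 (-5.52 ± 0.263), the long noncoding RNA CASC19 (-5.42 ± 0.227), TM4SF18 (-5.41 ± 0.0966), the dopamine receptor DRD1 (-5.13 ± 0.329) and the hexokinase family gene HKDC1 (-4.19 ± 0.240) fell. Adjusted p was at most 1.34e-07 for these 12 genes. MYC fell (-0.28 ± 0.0721, adjusted p = 0.00113) and HEXIM1 rose (1.19 ± 0.0528, adjusted p = 1.52e-21). CDK8 rose (0.23 ± 0.0639, adjusted p = 0.0026), which was lost without DKO-C1 JQ1 replicate 1 (adjusted p = 0.0547) and with ERCC factors (-0.0337, adjusted p = 0.903), and CDK19 was at 0.18 ± 0.0782 (adjusted p = 0.0529).

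Among the integrated stress response genes, 19 of 24 fell and 2 rose (19 and 3 adjusted over the list alone, camera adjusted p = 3.78e-14). STC2 (-2.28 ± 0.0710), TRIB3 (-1.74 ± 0.0758) and SLC7A11 (-2.20 ± 0.0990) fell. Among the replication-dependent histone genes, 12 of 13 rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 2.51e-10). HIST1H1C (2.56 ± 0.104) and HIST1H2BD (3.06 ± 0.167) rose. Among the mitotic genes, 26 of 30 fell and 0 rose (26 and 1 adjusted over the list alone, camera adjusted p = 2.25e-08). The mitotic motor KIF20A (-0.90 ± 0.0524) and the kinases AURKA (-0.84 ± 0.0536) and PLK1 (-0.82 ± 0.0615) fell. Among the autophagy and lysosome genes, 19 of 26 rose and 3 fell (19 and 3 adjusted over the list alone, camera adjusted p = 7.03e-08). NEU1 (1.78 ± 0.0774), MAP1LC3B (1.0 ± 0.0524) and ATG2A (1.43 ± 0.0860) rose. Among the mesenchymal genes, 11 of 18 fell and 2 rose (11 and 2 adjusted over the list alone, camera adjusted p = 1.5e-06). TAGLN (-2.59 ± 0.0719), FN1 (-1.23 ± 0.0775) and the actin-binding caldesmon CALD1 (-1.05 ± 0.0698) fell.

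Among the BET and P-TEFb genes, 8 of 16 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.000243). Among the NF-kappaB inflammatory genes, 11 of 18 fell and 4 rose (11 and 4 adjusted over the list alone, camera adjusted p = 0.0237, 0.13 with an estimated correlation). Among the immediate early genes, 11 of 21 rose and 4 fell (12 and 4 adjusted over the list alone, camera adjusted p = 0.0119, 0.583 with an estimated correlation). Among the cholesterol synthesis genes, 14 of 23 rose and 2 fell (14 and 2 adjusted over the list alone, camera adjusted p = 0.00036). Among the MYC-driven ribosome biogenesis genes, 20 of 36 fell and 1 rose (20 and 2 adjusted over the list alone, camera adjusted p = 0.00846, 0.577 with an estimated correlation). Among the YAP/TEAD target genes, 14 of 22 fell and 1 rose (14 and 1 adjusted over the list alone, camera adjusted p = 1.06e-05, 0.171 with an estimated correlation). Among the neural marker genes, 4 of 6 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.00108). The neural marker MAP2 had 7.73 ± 0.645 CPM without and 51.4 ± 1.29 CPM with JQ1. On genes with little shared sequence alone, the BET and P-TEFb, immediate early and MYC-driven ribosome biogenesis lists were no longer called. With an estimated correlation on this set, the calls for the BET and P-TEFb genes (adjusted p = 0.126) and cholesterol synthesis genes (0.126) were lost. In all, 8643 of 17198 genes were called for JQ1 in DKO-C1, 4281 higher and 4362 lower, 1814 at least 2-fold (534 up, 1280 down). ERCC factors gave a split in which 928 were higher and 4958 lower.

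The JQ1 responses of DKO-C1 and control cells were tested for a difference. As DKO-C2 got no JQ1, a difference may stem from the kinases or from the subline. The response was more positive in DKO-C1 for the vitamin D hydroxylase CYP24A1 (1.75 ± 0.0823), C6orf223 (1.93 ± 0.269), EGR1 (1.89 ± 0.411) and NRP1 (1.73 ± 0.394), and for the pseudogene BMPR1APS1 (3.54 ± 0.928), which shares sequence with its parent and had 0.0179 ± 0.0310 CPM, from 1 count, in DKO-C1 without JQ1. It was more negative for TAGLN (-2.69 ± 0.160), EDN1 (-3.44 ± 0.483), DCLK1 (-2.54 ± 0.344), NWD1 (-2.32 ± 0.621) and BTBD19 (-2.16 ± 0.280). FGF1, with a fitted difference of -4.70 ± 1.247, had 0.179 ± 0.0646 CPM in control and 0.0760 ± 0.0869 CPM with JQ1, and 6.72 ± 0.294 CPM in DKO-C1 and 0.109 ± 0.0763 CPM with JQ1. TAGLN had 3.20 ± 0.112 CPM in control and 3.44 ± 0.292 CPM with JQ1 (n = 3 each), and 106 ± 5.10 CPM in DKO-C1 (n = 3) and 17.7 ± 0.489 CPM with JQ1 (n = 2). For these 11 genes adjusted p was at most 0.0119. MYC differed by 0.58 ± 0.0938 (adjusted p = 2.68e-05), with a smaller fall in DKO-C1 (150 to 124 CPM) than in control (499 to 275). HEXIM1 was at -0.0469 ± 0.0717 (adjusted p = 0.791). CDK8 (0.17 ± 0.0844, adjusted p = 0.227) and CDK19 (-0.23 ± 0.107, adjusted p = 0.206) were not called. Some of these calls rest on single libraries; where DKO-C1 with JQ1 is left with 1 library, it is assumed to vary like the other groups. BMPR1APS1 was lost without DKO-C1 replicate 2 (3.09, adjusted p = 0.0522) or DKO-C1 JQ1 replicate 1 (3.37, adjusted p = 0.0893), and NRP1 without the latter (1.31, adjusted p = 0.161). EGR1 was lost without DKO-C1 JQ1 replicate a (1.27, adjusted p = 0.0579) or with only the libraries compared in the fit (adjusted p = 0.0574), FGF1 without control JQ1 replicate 2 (-3.47, adjusted p = 0.403), and NWD1 without control JQ1 replicate 3 (-2.03, adjusted p = 0.11) or DKO-C1 JQ1 replicate a (-2.08, adjusted p = 0.0558). With ERCC factors the calls of MYC (0.68, adjusted p = 0.138), BMPR1APS1 (3.66, adjusted p = 0.0656) and NWD1 (-2.22, adjusted p = 0.0789) were lost.

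Here rose and fell stand for a more positive and a more negative response in DKO-C1. Of 23 cholesterol synthesis genes, 19 rose and 1 fell (21 and 1 adjusted over the list alone, camera adjusted p = 3.27e-36). Among them were IDI1 (0.80 ± 0.0786), which shares sequence with another gene, and MVD (0.92 ± 0.0913). Of 30 mitotic genes, 21 fell and 0 rose (26 and 0 adjusted over the list alone, camera adjusted p = 9.16e-33). KIF20A (-1.03 ± 0.0684), AURKA (-0.62 ± 0.0713) and ANLN, a cytokinesis gene (-0.60 ± 0.0786), were among them. Of 22 YAP/TEAD target genes, 13 fell and 0 rose (19 and 0 adjusted over the list alone, camera adjusted p = 8.81e-15). AXL (-0.70 ± 0.0986), NUAK2 (-1.22 ± 0.192) and CTGF (-1.96 ± 0.256) fell. Of 24 integrated stress response genes, 11 fell and 0 rose (12 and 0 adjusted over the list alone, camera adjusted p = 2.06e-13). They included STC2 (-0.87 ± 0.0902) and CHAC1 (-2.0 ± 0.207). Of 16 NRF2 antioxidant genes, 6 fell and 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 7.66e-10). SLC7A11 (-1.06 ± 0.127) and, with overlapping or shared sequence, NQO1 (-0.82 ± 0.0651) and OSGIN1 (-1.36 ± 0.112) were among them. With ERCC factors AURKA (-0.52, adjusted p = 0.492), ANLN (-0.50, adjusted p = 0.538), AXL (-0.60, adjusted p = 0.301), STC2 (-0.76, adjusted p = 0.0802) and NQO1 (-0.72, adjusted p = 0.103) kept their direction and were no longer called.

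Of 26 p53 target genes, 7 fell and 1 rose (8 and 1 adjusted over the list alone, camera adjusted p = 0.000983). Of 13 fatty acid synthesis genes, 6 rose and 0 fell (7 and 1 adjusted over the list alone, camera adjusted p = 1.48e-09). Of 13 replication-dependent histone genes, 2 rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.00762, 0.0652 with an estimated correlation). Of 18 mesenchymal genes, 8 fell and 1 rose (10 and 1 adjusted over the list alone, camera adjusted p = 2.97e-09). Of 27 nuclear-encoded oxidative phosphorylation genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.00762, 0.518 with an estimated correlation). On genes with little shared sequence alone, the replication-dependent histone and nuclear-encoded oxidative phosphorylation lists were no longer called. With an estimated correlation on this set, the calls for the p53 target genes (adjusted p = 0.136) and NRF2 antioxidant genes (0.0714) were lost. In all, 1470 of 17198 genes had a different response, 663 more positive and 807 more negative in DKO-C1, 168 at least 2-fold (83 and 85). With ERCC library factors the split was 79 higher and 58 lower, and with only the libraries compared in the fit it was 460 and 1259. Leaving out 1 library gave 924 to 1436 genes, the lowest without DKO-C1 JQ1 replicate 1.

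**Figure D3:**
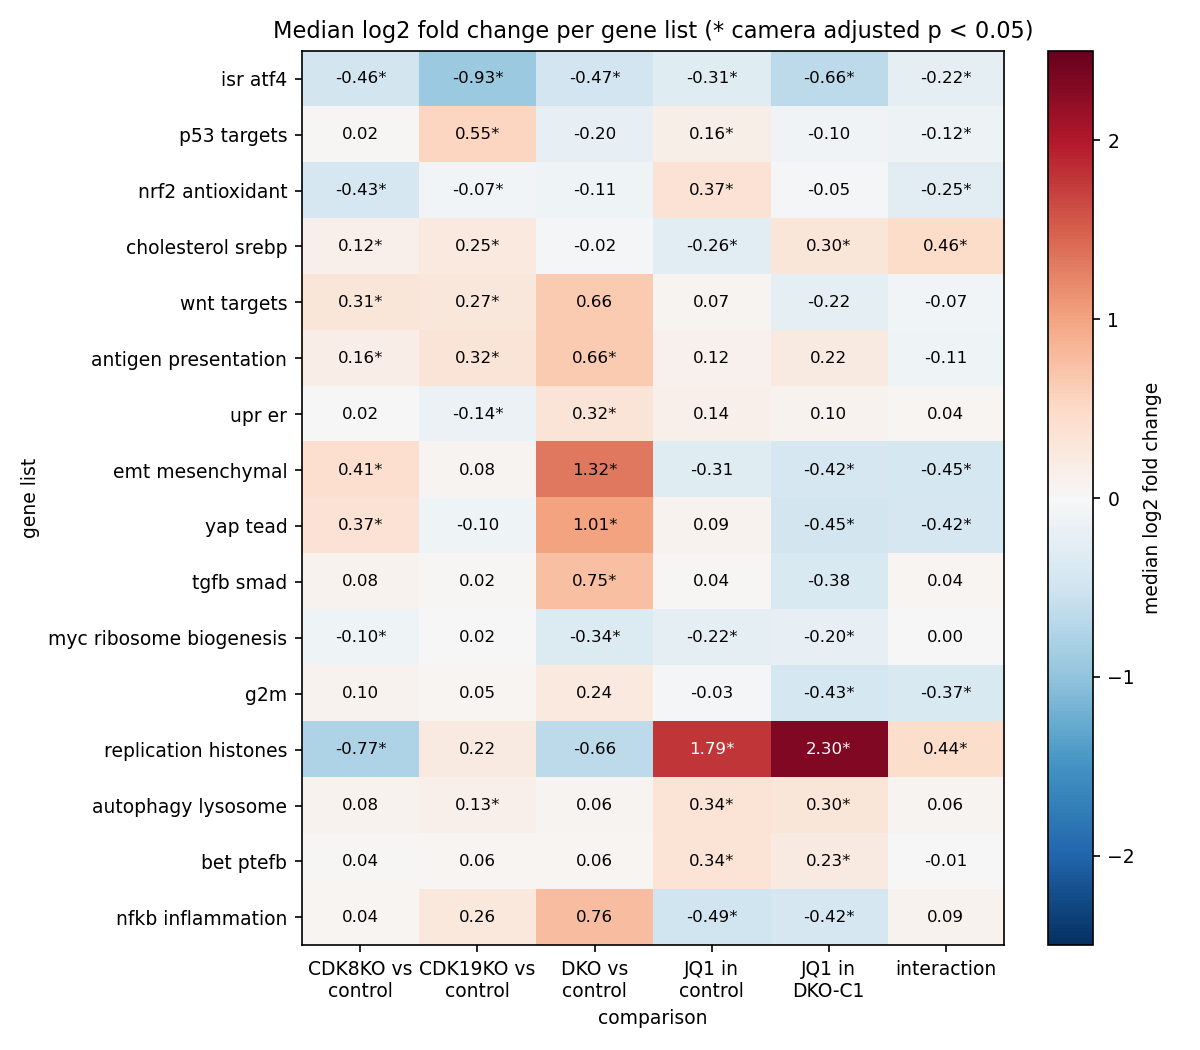
Median log2 fold change of 16 gene lists (lines) in 6 comparisons (columns), relative to the median gene, with an asterisk where camera's adjusted p with its preset correlation is under 0.05. Mesenchymal genes had a median of 1.32 in DKO and -0.42 for JQ1 in DKO-C1.

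**Figure D4:**
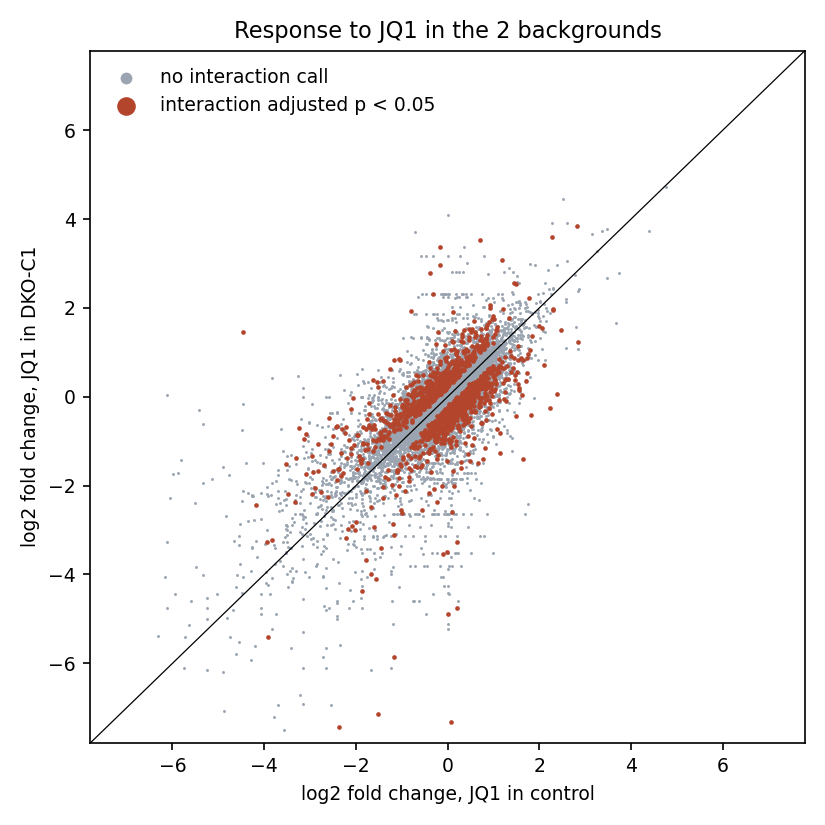
Log2 fold change of each tested gene on JQ1 in DKO-C1 (vertical axis) against that in control cells (horizontal axis), with the genes called for the difference in red. The 1470 red genes lie off the diagonal, and Pearson's r across all genes is 0.739.

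The JQ1 responses of control and DKO-C1 cells, which share no libraries, were compared across genes, which are not independent replicates. 3384 genes rose and 3415 fell in both, 97.9% of those called in both; independent calls would give 1151 and 1267. Pearson's r was 0.739 and Spearman's rho 0.743, and r was 0.820 over genes with little shared sequence. Of 1952 genes that JQ1 moved at least 2-fold in control cells, 1508 were called the same way in DKO-C1 and 4 the opposite way. 249 of the 1952 differed in response. Among the 4 were CTGF, AC008429.1 and PYURF, named after seeing their values. PYURF had 0.0885 CPM in control cells and 0 with JQ1, too few counts for a response.

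The sublines of each knockout were compared to ask how far they share their changes. 3789 genes were called the same way in both CDK8KO sublines and 177 in opposite ways, with 3643 genes differing between the sublines (r = 0.653, 0.664 over genes with little shared sequence). For CDK19KO these counts were 3128, 1147 and 8246 (r = 0.362, 0.287 over that set). For DKO these counts were 8366, 37 and 1614 (r = 0.957, 0.917 over that set). These r values are across genes and all share the control libraries. In data simulated with no effect, shared controls alone gave r = 0.494 for CDK8KO, 0.491 for CDK19KO and 0.494 for DKO with 0 genes called in both by edgeR, so the calls rather than r carry the comparison. The covariance was 0.195, 0.143 and 2.00, against 0.0299, 0.0297 and 0.0292 simulated.

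Of 899 genes with little shared sequence that changed at least 2-fold in DKO, 581 were called the same way and 40 the opposite way in CDK8KO. For CDK19KO these counts were 311 and 141, and 187 were called in neither. Across genes with little shared sequence r was 0.690 between CDK8KO and DKO, 0.131 between CDK19KO and DKO, and 0.212 between the single knockouts. Over all tested genes it was 0.369, 0.0842 and 0.300. Simulated data with no effect and the same shared controls gave 0.664, 0.664 and 0.657. Over all genes r was -0.00231 between DKO and JQ1 in control cells, and -0.0762 between DKO-C2 and JQ1 in DKO-C1, which share no libraries. It was 0.0998 and 0.180 between JQ1 in control cells and CDK8KO and CDK19KO, and -0.0486 and 0.0904 between JQ1 in DKO-C1 and these knockouts. JQ1 in control cells shares the control libraries with DKO, CDK8KO and CDK19KO. Simulated data with no effect gave 0.570, 0.570 and 0.569 for these relations, so r alone is no measure of a shared response. Their covariance was -0.00262, 0.0392 and 0.0739, against 0.0296, 0.0300 and 0.0299 simulated. These 10 relations and the 3 between sublines have no p values, as genes are not independent.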

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

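The tests of what the ERCC shares reflect were chosen after the result was seen; the tests between the JQ1 responses and between sublines were planned. 1470 genes differed in their JQ1 response between DKO-C1 and control cells by edgeR's test of the difference. The difference in log2 fold change was 3.54 for BMPR1APS1, 1.93 for C6orf223, 1.89 for EGR1, 1.75 for CYP24A1 and 1.73 for NRP1. It was -4.70 for FGF1, -3.44 for EDN1, -2.69 for TAGLN, -2.54 for DCLK1, -2.32 for NWD1 and -2.16 for BTBD19. Among members of the lists it was 0.80 for IDI1 and 0.92 for MVD, -1.03 for KIF20A, -0.62 for AURKA and -0.60 for ANLN, and -0.70 for AXL, -1.22 for NUAK2 and -1.96 for CTGF. It was -0.87 for STC2, -2.0 for CHAC1, -1.06 for SLC7A11, -0.82 for NQO1 and -1.36 for OSGIN1, and 0.58 for MYC. The fitted values of BMPR1APS1, FGF1 and EDN1 rest on groups with few counts and are no bounds. With ERCC factors the calls of BMPR1APS1, NWD1, AURKA, ANLN, AXL, STC2, NQO1 and MYC were lost. DKO-C1 with JQ1 has 2 libraries; without its replicate 1, 924 genes differed.

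By camera with its preset correlation, these lists differed between the responses: cholesterol synthesis (adjusted p = 3.27e-36) and fatty acid synthesis (1.48e-09), with a more positive response in DKO-C1, and mitotic genes (9.16e-33), YAP/TEAD targets (8.81e-15), the integrated stress response (2.06e-13), NRF2 antioxidant genes (7.66e-10), mesenchymal genes (2.97e-09) and p53 targets (0.000983), with a more negative one. Replication-dependent histones (0.00762) and nuclear-encoded oxidative phosphorylation genes (0.00762) had a more positive response, and these calls were lost with an estimated correlation. Sublines C1 and C2 differed in 3643 genes for CDK8KO, 8246 for CDK19KO and 1614 for DKO.

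ERCC counts, which the comparisons do not use, stood above the control level in all other groups. They were 1.17% ± 0.102 of gene counts (SD, n = 3) in control, at most 1.252%, and 1.44% in control with JQ1, 2.65% and 2.87% in CDK8KO-C1 and C2, 4.04% and 3.38% in CDK19KO-C1 and C2, 2.39% and 2.04% in DKO-C1 and C2, and 2.82% in DKO-C1 with JQ1. Pipetting error of single libraries is argued against, since the variance between groups was 35.1 times that within groups (permutation p = 0.0001, the smallest that 10000 permutations can give). Whether more spike-in was added to a group or its cells held less RNA cannot be told apart, as no measure of RNA per cell is given; the median gene under ERCC factors stood at -0.92 in DKO, above its place in either single knockout (-1.23 and -1.67), which either allows. Loss of the kinases lowering the RNA content stays an untested biological explanation.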

How the results depend on the processing

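Tests on protein-coding genes or on genes with little shared sequence, and ERCC factors for the single knockouts, CDK8KO against CDK19KO, DKO beyond the sum and the counts in both sublines, were chosen after seeing the data. All 203 values of named genes that passed the test kept their direction and call with DESeq2 size factors, no filter, DESeq2, limma voom and the block for the replicate number, as did the 200 that a minimum of 5 CPM left, the 164 with little shared sequence and the 201 that are protein-coding. The block gave 6826 genes for CDK8KO, and 0 of 63 pairs of same-numbered libraries in different groups had r over 0.1. With only the libraries compared 202 of 203 kept their call, with C1 alone 118 of 120, with C2 alone 116 of 120, and with 1 library left out 1940 of 1950 values, the others being weaker except AXIN2 in CDK19KO-C1 (-0.14). With ERCC factors 172 of 203 kept their call and direction, 12 were weaker and 19 reversed, and the called genes numbered 16258 for CDK8KO, 16849 for CDK19KO, 12561 for CDK8KO against CDK19KO, 16508 for DKO beyond the sum, 137 for the interaction, and 15461, 16324 and 13257 in both sublines of CDK8KO, CDK19KO and DKO. The reversed values were -0.88 for CDK19, -0.51 for COL6A1 and -0.56 for COL6A2 in CDK8KO; in CDK19KO -1.51 for CDK8, -0.28 for CDKN1A, -0.68 for DDB2, -0.55 for PHLDA3, -1.18 for LSS, -1.12 for BMP4, -0.58 for DKK1, -1.19 for AXIN2, -1.21 for TAPBP and -1.12 for TAP1. In DKO they were -0.51 for CDK19, -0.0667 for HLA-B and -0.34 for B2M, and for CDK8 0.13 in CDK8KO against CDK19KO, 1.58 beyond the sum and -0.0337 for JQ1 in DKO-C1; of these HLA-B and CDK8 in CDK8KO against CDK19KO and for JQ1 in DKO-C1 were not called in either direction with ERCC factors. The cause was not tested. At least 2-fold were 590 genes in CDK8KO, 664 in CDK19KO, 2858 in DKO, 757 in CDK8KO against CDK19KO, 2946 beyond the sum, 1952 for JQ1 in control, 1814 for JQ1 in DKO-C1 and 168 for the interaction. With fewer genes tested, those with little shared sequence, 6542 were called in DKO, 6138 beyond the sum and 5173 in both DKO sublines. Leaving out 1 library gave 5808 to 6654 genes for CDK8KO, 6230 to 7336 for CDK19KO, 9717 to 10784 for DKO, 7492 to 8022 for CDK8KO against CDK19KO, 9526 to 10587 beyond the sum, 8882 to 9064 and 7178 to 8160 for JQ1 in control and DKO-C1, and 924 to 1436 for the interaction. Lists called with an estimated correlation were 4 in CDK8KO, 6 in CDK19KO, 1 in DKO, 3 in CDK8KO against CDK19KO, 4 beyond the sum and 3 for JQ1 in control, and 37 of 92 list calls held; by fry they were 24 in CDK19KO, 25 in DKO, 33 in CDK8KO against CDK19KO, 25 beyond the sum, and 22 and 25 for JQ1 in control and DKO-C1. Fry does not compare a list with other genes. On genes with little shared sequence they were 8 in CDK8KO, 5 in CDK19KO, 7 in CDK8KO against CDK19KO and 7 for JQ1 in control, and 59 of 90 held. Pearson's r across genes, over genes of at least 5 CPM and over genes with little shared sequence, was 0.163 and 0.212 for CDK8KO and CDK19KO, 0.378 and 0.690 for CDK8KO and DKO, 0.0372 and 0.131 for CDK19KO and DKO, 0.0245 and 0.0435 for DKO and JQ1 in control, 0.856 and 0.820 for the JQ1 responses, -0.0604 and -0.162 for DKO-C2 and JQ1 in DKO-C1, 0.0495 and 0.0558 and 0.128 and 0.151 for JQ1 in control with CDK8KO and CDK19KO, and -0.0559 and -0.0793 for JQ1 in DKO-C1 with CDK8KO. With 1 library left out these ran, in the same order, from 0.287 to 0.352, 0.362 to 0.393, 0.0711 to 0.121, -0.00626 to 0.0219, 0.680 to 0.739, -0.0997 to -0.0145, 0.0892 to 0.137, 0.170 to 0.212 and -0.0602 to -0.0350. Of genes with the smallest simulated change, 26% were called for the interaction and 46.0% to 68.0% for the other comparisons, so small changes can be missed; the part of depth in this was not tested.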

Other observations

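The tests on pseudogenes, on CDK19 and on other splits of the samples were chosen after the results were seen, as were the genes named in the next sentences, whereas the lists were not. Of 28 interferon response genes, 12 rose and 3 fell (12 and 4 adjusted over the list alone, camera adjusted p = 0.0587) in CDK19KO and 18 rose and 4 fell (19 and 4 adjusted over the list alone, camera adjusted p = 0.0847) in DKO. IFIT3, an antiviral effector, rose in DKO (1.57 ± 0.186), as did OAS3, which senses double-stranded RNA (0.75 ± 0.0410), and OAS1 was called higher in CDK19KO, against control libraries with too few counts for a fold. The cytokine gene IL32 fell in CDK19KO (-5.24 ± 0.331) and DKO (-4.61 ± 0.303), and in CDK8KO, where too few counts were left for a fold. Of the markers of other tissues, SERPINA1 (liver) rose in DKO (3.78 ± 0.124), with group means of 1.57 CPM in control and 23.9 CPM and 19.8 CPM in DKO-C1 and C2; the blood and endothelial lists had 1 and 2 tested members and were not tested as lists.

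Of 26 core Mediator subunits, 5 rose and 7 fell (5 and 7 adjusted over the list alone, camera adjusted p = 0.801) in DKO, with MED27 at 0.85 ± 0.0700. Of 7 kinase module genes, 2 rose and 3 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.368) in CDK19KO, where MED13L (-0.44 ± 0.0480) and MED12 (-0.33 ± 0.0550) fell. The hypoxia, apoptosis and Notch lists were called in none of the 8 comparisons by camera. In DKO, of 23 hypoxia genes 11 rose and 6 fell (11 and 6 adjusted over the list alone, camera adjusted p = 0.55), of 22 apoptosis genes 11 rose and 4 fell (11 and 4 adjusted over the list alone, camera adjusted p = 0.451), and of 14 Notch genes 2 rose and 3 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.894).

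Processed pseudogenes were far lower in the 8 libraries labelled DKO than in the other 18. A difference in how reads shared between copies were counted in these libraries is a candidate explanation: the median log2 fold change of 265 pseudogenes that share at least 50% of their words was -4.68, and it lay below that of pseudogenes sharing under 10% by a difference of -1.49 (95% bootstrap interval -1.83 to -1.26, 1000 draws). The 470 pseudogenes sharing under 10% still had a median of -3.19 (95% interval -3.32 to -2.89). This does not decide on reads that match 2 copies equally well. The share of words does not give the share of counts, which can come from the small shared part. Loss of both kinases, the biological explanation, and a difference in handling or counting of these libraries cannot be told apart, as 0 libraries of either kind had a share in the range of the other. POLR2F and PYURF parted the libraries as well, upward, and the same limit holds for them. Their highest group means were 0.463 and 0.0885 CPM in groups not labelled DKO, and their lowest were 50.4 and 26.8 CPM in groups labelled DKO.

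CDK19 RNA was not below control in the libraries labelled DKO, relative to the median gene. Reads shared with another gene are argued against, since CDK19 shares 0.103% of its 50-base words and overlaps no exon of another gene on its strand. Cells without an edited CDK19 gene and an edit that leaves the RNA level in place, the biological explanation, cannot be told apart, as the labels give no edit and counts per gene do not show one. CDK19 in DKO minus CDK8KO was 0.0620 ± 0.0497 (adjusted p = 0.287), which is smaller than the difference between the CDK19KO sublines (0.43 ± 0.0792).

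Other splits of the same libraries, fitted alone, were counted for each number of genes called by edgeR, the real split included. For CDK8KO 1 of 84 splits gave as many (5322 genes, highest other 2485), for DKO 1 of 84 splits (9067, highest other 82), for CDK8KO against CDK19KO 1 of 100 splits (3948, highest other 0) and for DKO beyond the sum 1 of 100 splits (7496, highest other 1857). For CDK19KO 3 of 84 splits gave as many (2746, highest other 4884). These shares are under 0.05, which excludes a chance assignment of single libraries only: the median of the other splits was 0 genes, splits by whole sublines are too few to exclude chance for the comparisons of 3 or 4 groups, and were not run for DKO beyond the sum. Setting CDK19KO-C1 alone against the rest gave 4884 genes and CDK19KO-C2 alone 3949, more than the 2746 for control alone, which points to a structure by subline. For genes called in both sublines, 1 of 100 splits gave as many for CDK8KO (4601, highest other 3123), 1 of 100 splits for CDK19KO (3340, highest other 2755) and 1 of 100 splits for DKO (7567, highest other 7398). For JQ1 in control the 10 splits are too few for a share under 0.05 (9116, highest other 0); JQ1 in DKO-C1 and the interaction have a group of 2 and were not split.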
